A study of Drosophila melanogaster with 12 samples.

How the data were processed

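RNA was measured in eye discs of late (L3) Drosophila melanogaster larvae on Affymetrix arrays, 1 array per sample. Per the labels' protocols, total RNA was extracted with Trizol, purified on RNeasy columns and turned into biotin-labelled cRNA from 6 ug of RNA. The labels give 4 genotypes with 3 biological replicates each, 12 arrays in all: Canton S, rbf120a, wtsX1Lats and rbf120a wtsX1Lats. Per the series' design text, the discs were mosaic and mostly made of mutant cells. The labels call the replicates biological but do not say how many animals or discs went into each.

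The authors deposited 1 table of log2 values, with 18952 probe sets. The log2 scale was read from the values, which lay between 3.55 and 14.53 over all arrays; the method of summary and normalization is not given in the sources used here. The values were already brought to nearly the same distribution in all arrays: sorted values differed from their mean distribution by 0.026 on average and by at most 0.175. Array medians lay between 5.76 and 5.86. Scanner files and detection calls were not used here, so background could not be told per probe set, and the number of arrays limits the precision.

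Of the probe sets, 183 were controls, 13646 were listed with 1 gene, 402 with several genes and 4721 with no gene in the annotation used here. Names came from the platform annotation, and 13543 probe sets were matched to a current gene table (Release 6 plus ISO1 MT), which was used for names and chromosomes alone, since the files name no genome build. Each of the 11982 genes was represented by its probe set with the highest mean over the 12 arrays; 1094 genes had more than 1 probe set. List members that the annotation did not name, such as CycA, stg, polo and E2f, were not analysed here.

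Changes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend) in a single fit of 4 group means over all 12 arrays, which leaves 8 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method over the 11982 genes. Adjusted p under 0.05 counted as changed. Every adjusted p for a gene is from this test. The contrasts were each mutant group against Canton S, the double mutant against each single mutant, and the interaction, which is the rbf120a change in the wtsX1Lats background minus the rbf120a change in the Canton S background. Errors of log2 changes are standard errors of the fit and errors of levels are SDs over 3 arrays. The pooled spread assumes that the 4 groups vary alike. The median SD within a group was 0.13 in Canton S, 0.10 in rbf120a, 0.17 in wtsX1Lats and 0.08 in the double mutant.

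For tests of gene groups, 30 lists were written before the data were examined: E2F and DNA replication, mitosis, Hippo target genes, Hippo pathway components, photoreceptor and cone cell differentiation, retinal determination, morphogen and furrow signalling, Notch targets, apoptosis, DNA damage response and repair, JNK and wounding, ribosome biogenesis, ribosomal proteins, heat shock, antimicrobial peptides, ecdysone response and stage, glycolysis, oxidative phosphorylation, germline genes, male sex markers, testis, fat body, blood cells, muscle, trachea, salivary gland, brain and glia, antennal disc, gut, and eye disc markers of late differentiation. Lists were tested with camera at a preset correlation of 0.01, with camera at a correlation estimated for each list, and with fry; p-values were adjusted over the 30 lists of a contrast. fry tests whether the genes of a list move, on balance, one way and does not compare them with other genes. No call made with the preset correlation held with the estimated one.

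The rule for named genes was also fixed beforehand. It took Rbf and wts throughout, the 8 largest rises and the 8 largest falls of each contrast among genes with adjusted p under 0.05 whose groups did not overlap and that have a name of their own, 6 each way for the interaction with adjusted p alone, and up to 4 members with the smallest p per list and contrast. Groups of 3 fail to overlap in 10% of genes by chance.

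The test was checked on simulated data, a single draw for each comparison, with 67, 67 and 66 genes changed by 0.5, 1 and 2. Each of the 11982 genes kept its mean and its pooled SD, scaled by a factor per group taken from the group's median SD. Single outlying arrays were not simulated. A change of 1 on the log2 scale was recovered in 85.1% of the changed genes for rbf120a against Canton S, 85.1% for wtsX1Lats against Canton S, 89.6% for the double mutant against Canton S, 91.0% for the double mutant against rbf120a, 88.1% for the double mutant against wtsX1Lats and 73.1% for the interaction. A change of 0.5 was recovered in 64.2%, 41.8%, 38.8%, 40.3%, 46.3% and 20.9% of the genes, in the same order. In the simulated comparison of wtsX1Lats with Canton S, 45 of 195 calls were false, above the nominal rate; that group varies more than the pooled spread. In the others, false calls were 11 of 173, 2 of 153, 0 of 151, 17 of 173 and 7 of 130, in the order above. The 17 of 173, for the double mutant against wtsX1Lats, also lay above the nominal rate, and 11 of 173 and 7 of 130 slightly so. A list shifted by 0.5 was recovered by camera (adjusted p = 8.88e-30), and 0 of the other 29 lists were called. Genes were drawn independently of each other there, whereas the estimated correlation within the E2F and DNA replication list was 0.774 in the data. The check therefore does not cover lists whose genes move together.

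Alternatives covered the normalization, dim genes, the choice of probe set, the variance trend, the replicate number and the array number as blocks, arrays 1 to 8 alone, array weights, each array left out in turn (where several removals ended a call, the text names the one with the highest adjusted p), separate fits per comparison, a fold minimum and all probe sets. Shared control arrays were allowed for by 100 simulations of unchanged groups. Figures were drawn with matplotlib.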

Results

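Expression was measured in eye discs of late (L3) larvae of 4 genotypes. Canton S is a standard wild-type strain. The other groups carried rbf120a, an allele of the retinoblastoma family gene Rbf, wtsX1Lats, an allele of warts, which encodes the Hippo pathway kinase also known as Lats, or both. Rbf proteins restrain E2F transcription factors, and the Hippo pathway restrains growth through the co-activator Yorkie, so the comparison asks which genes change when either or both brakes are mutated. Each group had 3 arrays, and values are log2 signals.

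The targeted genes were examined first. Rbf (CG7413, X chromosome) had a mean of 9.45 ± 0.12 (SD, n = 3) in Canton S, 9.16 ± 0.05 in rbf120a, 9.50 ± 0.71 in wtsX1Lats and 9.19 ± 0.21 in the double mutant. Its change in rbf120a was -0.29 ± 0.26 (SE; adjusted p = 0.812). wts (CG12072, arm 3R) had means of 9.95 ± 0.10 (SD, n = 3), 9.73 ± 0.06, 9.70 ± 0.60 and 9.91 ± 0.13 in the same order, and its change in wtsX1Lats was -0.25 ± 0.22 (SE; adjusted p = 0.59). Neither change passed the test, and the labels do not say where the alleles lie relative to the probes, so these values do not check the labels. In replicates 1, 2 and 3, Rbf was at 9.53, 9.31 and 9.51 in Canton S, 9.13, 9.13 and 9.22 in rbf120a, 8.72, 9.67 and 10.10 in wtsX1Lats and 8.96, 9.36 and 9.26 in the double mutant. The rbf120a arrays thus lay below those of Canton S, and groups of 3 fail to overlap in 10% of genes by chance. wts was at 9.86, 10.05 and 9.95 in Canton S, 9.67, 9.73 and 9.78 in rbf120a, 9.08, 9.76 and 10.27 in wtsX1Lats and 9.76, 9.95 and 10.02 in the double mutant.

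**Figure D1:**
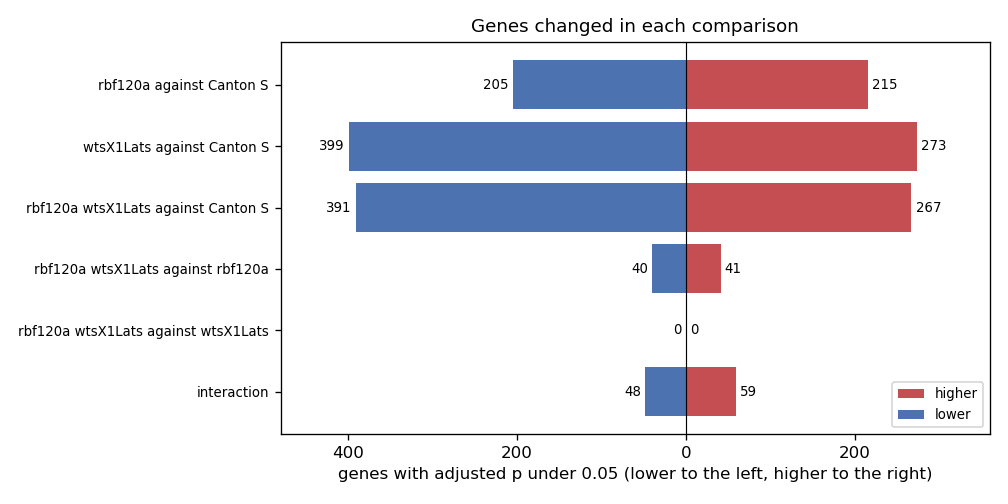
Number of genes with adjusted p under 0.05 in each comparison, with lower genes drawn to the left and higher genes to the right (x axis, number of genes). The 3 mutant groups differed from Canton S in 420, 672 and 658 genes, and the double mutant differed from wtsX1Lats in 0.

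The rbf120a group was set against Canton S first, and the design does not separate the allele from a difference between strains. Genes of DNA replication were higher in the mutant discs: of the 37 measured members of the E2F and DNA replication list, 18 rose and 0 fell (33 rose when adjusted over the list alone), with a median change of 1.04. Among them were the chromatin assembly factor subunit Caf1-105 (1.23 ± 0.15 SE, adjusted p = 0.000718), the DNA polymerase alpha subunit PolA1 (1.15 ± 0.14, adjusted p = 0.000613) and the ribonucleotide reductase subunit RnrL (1.15 ± 0.18, adjusted p = 0.00299). PolA1 went from 8.50 ± 0.19 (SD, n = 3) in Canton S to 9.65 ± 0.07 in rbf120a. The list passed camera (adjusted p = 3.48e-32), with adjusted p = 0.299 with an estimated correlation and 0.0202 by fry.

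Some mitosis genes rose to a lesser extent. Of 34 members 3 rose (13 adjusted over the list alone; median change 0.26; camera adjusted p = 5.71e-10, and adjusted p = 0.246 with an estimated correlation), among them borr (0.64 ± 0.13 SE) and aurB (0.75 ± 0.17) of the chromosomal passenger complex and thr (0.46 ± 0.11). None of these 3 calls survived every removal of an array, with adjusted p up to 0.0757, 0.143 and 0.18, each without rbf120a replicate 3. In the DNA damage response and repair list 1 of 22 genes rose (6 adjusted over the list alone), the mismatch repair gene Msh6 (0.92 ± 0.19, and adjusted p = 0.112 without rbf120a replicate 3). Its median change was 0.22 (camera adjusted p = 0.000817, and adjusted p = 0.406 with an estimated correlation).

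Outside the cell cycle, the largest rises were in Mal-A1 (a maltase, 2.98 ± 0.37 SE), LBR (the lamin B receptor, 2.76 ± 0.14), the zinc finger gene jim (2.32 ± 0.07), timeout (2.23 ± 0.27), the piRNA pathway gene krimp (2.22 ± 0.16), Gr61a (a gustatory receptor, 2.19 ± 0.23), Rbm13 (2.19 ± 0.17) and rpk (2.16 ± 0.25). krimp is a dim gene in Canton S, at 4.65 ± 0.06 (SD, n = 3). The piRNA gene AGO3 also rose (0.39 ± 0.08, and adjusted p = 0.0813 without rbf120a replicate 1). Only the probe set used for jim moved: its other probe sets changed by 0.13 and 0.08. The largest falls were in Mec2 (-3.26 ± 0.43), fat-spondin (-2.92 ± 0.34), Glt (-2.84 ± 0.15), the serpin Spn47C (-2.78 ± 0.61), the cuticle gene Cpr47Eb (-2.69 ± 0.32), Gal (-2.34 ± 0.35), the co-chaperone gene stv (-2.30 ± 0.22) and the phagocytosis receptor eater (-2.29 ± 0.30). Spn47C was no longer called without rbf120a replicate 1 (adjusted p = 0.119).

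Some blood cell genes were lower in rbf120a. Of 16 members 5 fell and 0 rose (8 adjusted over the list alone), with a median of -0.54 and camera adjusted p = 4.4e-07, and adjusted p = 0.246 with an estimated correlation. Hml (hemolectin) fell by 2.04 ± 0.24 SE, from 9.46 ± 0.51 (SD, n = 3) to 7.42 ± 0.10. The prophenoloxidase gene PPO1 (-2.03 ± 0.40) and the GATA factor gene srp (-2.01 ± 0.42) fell as well, though without Canton S replicate 1 their adjusted p were 0.0867 and 0.0954. The photoreceptor and cone cell list had a median of -0.21 with 0 of 27 members called; its camera adjusted p was 0.0193 (adjusted p = 0.736 with an estimated correlation) and 0.144 without Canton S replicate 2. The gut list had a median of 0.35 with Mal-A1 as its 1 called member (camera adjusted p = 0.0122, and adjusted p = 0.733 with an estimated correlation), its median in the arrays of rbf120a was -0.03, 0.04 and 0.96, and without replicates 1 and 3 the change was 0.526 and 0.002 (camera adjusted p = 8.92e-05 and 0.266).

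Of the genes changed in rbf120a, 221 changed the same way in all 3 mutant groups, among them LBR, Rbm13, rpk, Glt, stv and eater. The set also holds the DNA replication genes Orc1, Orc2, Prim2, PCNA, RnrL and Caf1-105 and the mitosis genes aurB and borr. In total 420 of 11982 genes changed, 215 higher and 205 lower, of which 184 by at least 1 on the log2 scale. The count was 197 without Canton S replicate 1, 216, 228 and 219 without rbf120a replicates 1, 2 and 3, and 632 without wtsX1Lats replicate 1.

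**Figure D2:**
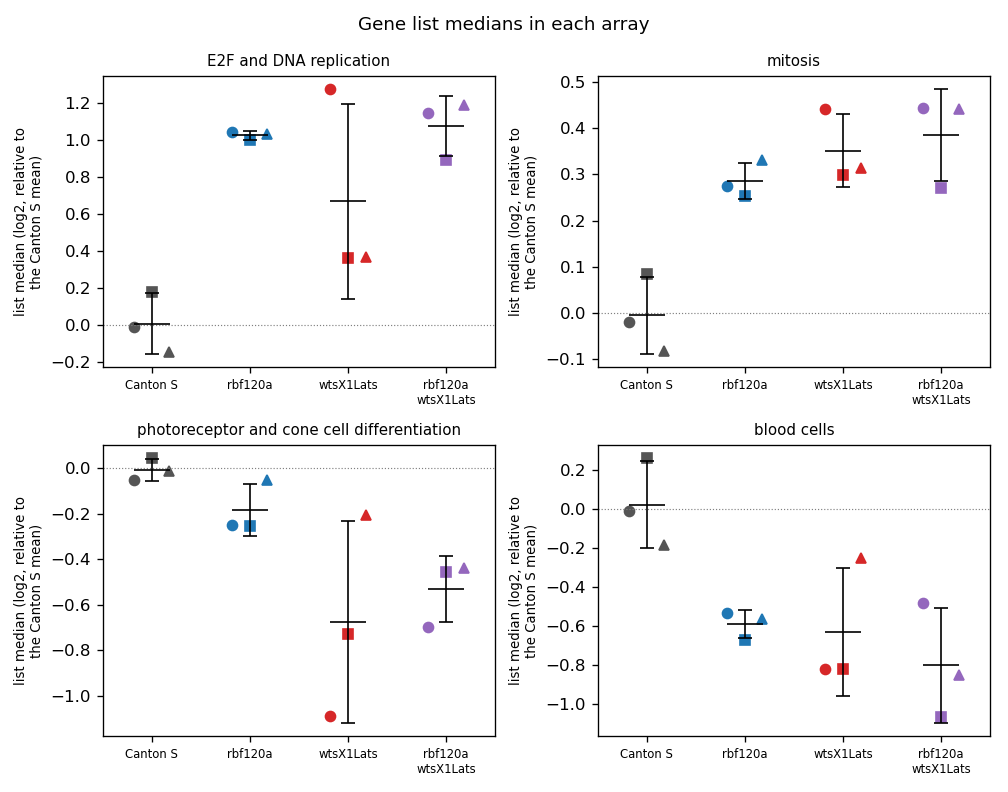
Median of 4 gene lists in each array (y axis, log2, relative to the Canton S mean of each gene), by genotype (x axis). Circles, squares and triangles are replicates 1, 2 and 3, horizontal lines are group means and error bars are SDs over 3 arrays. In wtsX1Lats the E2F and DNA replication median was 1.28 in replicate 1 and 0.36 and 0.37 in replicates 2 and 3.

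The wts allele without rbf120a was read from wtsX1Lats against Canton S, where allele and strain are not separated either. Some photoreceptor and cone cell genes were lower: of 27 members 6 fell and 0 rose (16 adjusted over the list alone), with a median of -0.53. Among them were sev, the receptor tyrosine kinase of the R7 cell (-1.48 ± 0.19 SE), the transcription factor genes gl (-1.60 ± 0.26) and sens (-1.13 ± 0.19) and the homeobox gene ro (-1.08 ± 0.19). sev went from 9.01 ± 0.34 (SD, n = 3) to 7.53 ± 0.17. The list's median was -1.09, -0.73 and -0.20 in the arrays of wtsX1Lats (-0.300 without replicate 1 and -0.875 without replicate 3 for the change), where the muscle list stood at -0.94, -0.46 and 0.93. The camera adjusted p was 3.59e-11, with adjusted p = 0.341 with an estimated correlation and 0.0368 by fry.

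Some mitosis and DNA replication genes were higher in the same discs. In the mitosis list 8 of 34 members rose and 0 fell (13 adjusted over the list alone; median 0.32), with aurB at 0.96 ± 0.17 SE, Incenp at 0.73 ± 0.14 and the kinesin gene ncd at 0.71 ± 0.14 (camera adjusted p = 1.33e-09, and adjusted p = 0.215 with an estimated correlation). In the E2F and DNA replication list 7 of 37 rose (30 adjusted over the list alone; median 0.66), including Prim2 (1.61 ± 0.29), Orc1 (1.47 ± 0.31) and Caf1-105 (0.67 ± 0.15). All 7 were also called higher in rbf120a and in the double mutant. The calls for Orc1 and Caf1-105 ended without Canton S replicate 1, at adjusted p of 0.0659 and 0.0978. This list passed camera (adjusted p = 6.33e-14, and adjusted p = 0.436 with an estimated correlation), and its array medians of 1.28, 0.36 and 0.37 were far apart (change of 0.343 without replicate 1).

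Some genes of 2 metabolic lists were higher. Of 10 glycolysis genes 4 rose (7 adjusted over the list alone; median 0.34; camera adjusted p = 0.000108, and adjusted p = 0.215 with an estimated correlation), namely Pgi (0.55 ± 0.09 SE), Gapdh1 (0.40 ± 0.07), Tpi (0.36 ± 0.08) and Pfk (0.48 ± 0.11). Tpi was at adjusted p = 0.116 without Canton S replicate 1 and Pfk at 0.081 without Canton S replicate 2. Of 16 oxidative phosphorylation genes 3 rose (11 adjusted over the list alone; median 0.30; camera adjusted p = 3.3e-06, and adjusted p = 0.36 with an estimated correlation). These were SdhC (0.40 ± 0.10), ox (0.44 ± 0.11) and COX4 (0.29 ± 0.07), and without Canton S replicate 1 their adjusted p were 0.0973, 0.136 and 0.137.

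Some neural genes and Notch targets were lower. In the brain and glia list 4 of 17 fell and 1 rose (8 and 2 adjusted over the list alone; median -0.37; camera adjusted p = 0.00132, and adjusted p = 0.215 with an estimated correlation). The neuroblast gene ase fell by 0.82 ± 0.14 SE, and the glial gene repo by 0.76 ± 0.17 (adjusted p = 0.0936 without Canton S replicate 1). Of 13 Notch targets 2 fell, E(spl)mdelta-HLH (-1.19 ± 0.25, and adjusted p = 0.0586 without Canton S replicate 2) and E(spl)m4-BFM (-1.15 ± 0.28, but -0.744 without wtsX1Lats replicate 1, and adjusted p = 0.0898 without Canton S replicate 1). The list's median was -0.31 (-0.65, -0.69 and 0.06 in the arrays of wtsX1Lats), with camera adjusted p = 0.00517, adjusted p = 0.5 with an estimated correlation, and 0.118 without wtsX1Lats replicate 2, and the change was -0.709 without replicate 3. The eye field gene Optix rose (0.60 ± 0.11) and dan fell (-0.68 ± 0.12). Among the blood cell genes 3 of 16 fell (5 adjusted over the list alone; median -0.59; camera adjusted p = 3.3e-06, and adjusted p = 0.215 with an estimated correlation): eater (-2.64 ± 0.30), Hml (-2.05 ± 0.24) and srp (-1.98 ± 0.42, and adjusted p = 0.0772 without Canton S replicate 1).

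Hippo target genes did not pass as a group: 0 of 10 were called, the median was 0.22 and the camera adjusted p was 0.0614 (adjusted p = 0.462 with an estimated correlation). This rests on single arrays. The list's medians in the arrays of wtsX1Lats were 0.013, 0.292 and 0.459, and the list passed without wtsX1Lats replicate 1 (change of 0.311, camera adjusted p = 0.000268) and without Canton S replicate 2 (0.192 and 0.0499), while without wtsX1Lats replicate 3 it was at 0.139 and 0.365. The target ex was at 9.83, 10.68 and 10.57 in wtsX1Lats replicates 1, 2 and 3, against 9.74, 10.26 and 9.67 in Canton S. Of the 18 targets written, 10 were measured, and th, wg, vn and dally were among those that were not.

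The largest rises were in Tektin-C (4.07 ± 0.14 SE), sut2 (3.21 ± 0.26), Hsc70-2 (3.16 ± 0.20), tut (3.02 ± 0.27), LBR (2.79 ± 0.14), retinin (2.75 ± 0.47), jim (2.16 ± 0.07) and Adk3 (2.13 ± 0.29). The other probe sets of jim changed by -0.01 and -0.27. Tektin-C went from 5.10 ± 0.15 (SD, n = 3) to 9.17 ± 0.09. The largest falls were in the zinc transporter gene Zip102B (-3.49 ± 0.68), Cpr47Eb (-2.98 ± 0.32), Mec2 (-2.87 ± 0.43), Glt (-2.79 ± 0.15), fat-spondin (-2.70 ± 0.34), eater, Appl (-2.50 ± 0.33) and stv (-2.47 ± 0.22). Zip102B varied widely within wtsX1Lats, at 7.12 ± 2.01 (SD, n = 3).

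In the simulated data 45 of 195 calls of wtsX1Lats against Canton S were false, above the nominal rate. The 221 genes that changed the same way in all 3 mutant groups are counted here too. In total 672 genes changed, 273 higher and 399 lower, of which 231 by at least 1. The count was 297 without Canton S replicate 1, 1596 without wtsX1Lats replicate 3, 181 in a fit over these 6 arrays alone, and 311 without wtsX1Lats replicates 1 and 3, a check chosen after seeing the data. In wtsX1Lats replicate 3 the 3' minus 5' log2 differences of the actin, GAPDH and eIF-4A controls were 1.70, 1.81 and 1.90, where the highest of the other 11 arrays were 0.82, 1.43 and 0.95.

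The double mutant was compared with Canton S. DNA replication genes rose about as much as in rbf120a: 24 of 37 rose and 0 fell (33 adjusted over the list alone), with a median of 1.10. PolA1 rose by 1.14 ± 0.14 SE, Caf1-105 by 1.20 ± 0.15 and RnrL by 1.19 ± 0.18. In the mitosis list 10 of 34 rose (19 adjusted over the list alone; median 0.37), with CycB3 at 0.63 ± 0.11 and aurB at 0.87 ± 0.17 (adjusted p = 0.0561 without the double mutant's replicate 1). The camera adjusted p were 5.31e-28 and 3.39e-15, with adjusted p = 0.26 and 0.166 with an estimated correlation. In the DNA damage response and repair list 3 of 22 rose (5 adjusted over the list alone), Msh6 (1.07 ± 0.19), Fancd2 (0.63 ± 0.13) and mus101 (0.92 ± 0.23), the last 2 without a call in the absence of the double mutant's replicate 1 (adjusted p = 0.0931 and 0.133). Its camera adjusted p was 0.000379 (adjusted p = 0.26 with an estimated correlation).

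Some Hippo target genes were higher. Of 10 members 2 rose (3 adjusted over the list alone; median 0.36; camera adjusted p = 0.00357, and adjusted p = 0.26 with an estimated correlation): ex, which encodes an upstream Hippo component and is itself a target, by 1.13 ± 0.21 SE, from 9.89 ± 0.32 (SD, n = 3) to 11.02 ± 0.01, and CycB by 0.47 ± 0.12 (adjusted p = 0.173 without the double mutant's replicate 1). CycE was at 0.77 ± 0.24 (adjusted p = 0.087). CycB is also in the mitosis list and CycE in the E2F and DNA replication list, and both lists rose in the same comparison. Among retinal determination genes, Optix (0.76 ± 0.11) and ey (0.91 ± 0.13) rose; the list as a whole did not pass (median 0.02, camera adjusted p = 0.393).

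Some genes of other lists were lower. In the photoreceptor and cone cell list 4 of 27 fell and 0 rose (15 adjusted over the list alone; median -0.50; camera adjusted p = 1.8e-09, and adjusted p = 0.275 with an estimated correlation): sev (-1.55 ± 0.19 SE), gl (-1.38 ± 0.26), ro (-0.91 ± 0.19) and sens (-0.92 ± 0.19). The calls for ro and sens ended without the double mutant's replicates 1 and 3, at adjusted p of 0.0718 and 0.0664. Of 13 Notch targets 2 fell (7 adjusted over the list alone; median -0.57; camera adjusted p = 0.000379, and adjusted p = 0.337 with an estimated correlation). In the brain and glia list 7 of 17 fell and 1 rose (9 and 1 adjusted over the list alone; median -0.51; camera adjusted p = 7.11e-05, and adjusted p = 0.18 with an estimated correlation), among them dpn (-1.15 ± 0.23) and loco (-0.51 ± 0.11). Without the double mutant's replicates 3 and 1 these were at adjusted p of 0.0561 and 0.08. Of 16 blood cell genes 5 fell (8 adjusted over the list alone; median -0.79; camera adjusted p = 1.75e-06, and adjusted p = 0.201 with an estimated correlation), including Hml (to 7.46 ± 0.30 SD, n = 3), eater (-2.33 ± 0.30 SE) and the collagen IV genes vkg (-0.99 ± 0.17) and Col4a1 (-1.29 ± 0.30, and adjusted p = 0.0991 without the double mutant's replicate 2).

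The largest changes were rises in Tektin-C (4.33 ± 0.14 SE), tut (3.33 ± 0.27), retinin (3.24 ± 0.47), Hsc70-2 (3.19 ± 0.20), sut2 (3.05 ± 0.26), LBR (2.91 ± 0.14), TwdlE (2.39 ± 0.36) and jim (2.37 ± 0.07), and falls in Spn47C (-3.45 ± 0.61), Cpr47Eb (-3.09 ± 0.32), fat-spondin (-2.78 ± 0.34), Mec2 (-2.74 ± 0.43), stv (-2.50 ± 0.22), Glt (-2.47 ± 0.15), eater and Gal (-2.29 ± 0.35). The other probe sets of jim changed by 0.51 and 0.43. In total 658 genes changed, 267 higher and 391 lower, of which 258 by at least 1. The count was 325 without Canton S replicate 1, 352, 415 and 297 without the double mutant's replicates 1, 2 and 3, 1080 and 1014 without wtsX1Lats replicates 1 and 3, and 1076 in a fit over these 6 arrays alone.

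**Figure D3:**
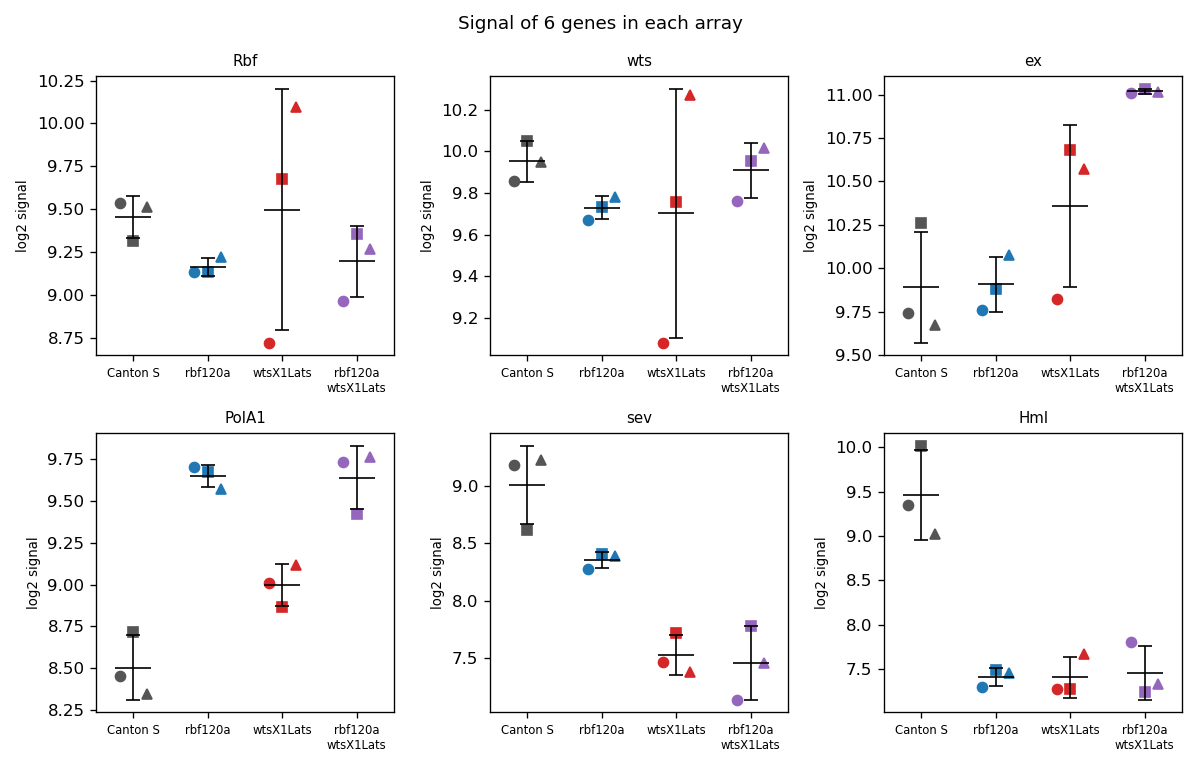
Log2 signal of Rbf, wts, ex, PolA1, sev and Hml in each array (y axis) by genotype (x axis). Circles, squares and triangles are replicates 1, 2 and 3, horizontal lines are group means and error bars are SDs over 3 arrays. ex was 11.02 ± 0.01 in the double mutant and 9.89 ± 0.32 in Canton S.

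What the wts allele adds to the rbf allele was read from the double mutant against rbf120a. The design does not separate the allele from a difference between strains here either. ex rose by 1.11 ± 0.21 SE (adjusted p = 0.0384, and 0.189 without rbf120a replicate 1), Optix by 0.72 ± 0.11 and ey by 0.86 ± 0.13, and the glial gene repo fell by 0.89 ± 0.17. Of these, Optix and repo were at adjusted p of 0.0671 and 0.189 without the double mutant's replicates 3 and 1, and ey at 0.0731 without rbf120a replicate 1. The E2F and DNA replication list did not move (median -0.01, 0 of 37 called, camera adjusted p = 0.711), and its median changed sign when the arrays were rescaled. The photoreceptor list had a median of -0.60 with 0 of 27 called (5 adjusted over the list alone; camera adjusted p = 4.39e-07, and adjusted p = 0.404 with an estimated correlation). Hippo targets (median 0.23), retinal determination (0.18), mitosis (0.12), Notch targets (-0.37), muscle (-0.65) and gut (-0.38) also passed camera, with adjusted p between 0.000723 and 0.00463, and with adjusted p = 0.404 or 0.412 with an estimated correlation; brain and glia (-0.38) was at 0.000131 and 0.335. Of these lists, called members were 1 of 10 Hippo targets (ex), 2 of 10 retinal determination genes (4 adjusted over the list alone) and 1 of 17 brain and glia genes (9), and 0 of 34, 13, 10 and 9 mitosis, Notch, muscle and gut genes (0, 2, 0 and 1). The gut list was at a change of -0.022 and camera adjusted p = 0.169 without rbf120a replicate 3, and mitosis at 0.070 and 0.0457 without the double mutant's replicate 1.

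The largest rises were again in Tektin-C (4.33 ± 0.14 SE), Hsc70-2 (3.12 ± 0.20), tut (3.11 ± 0.27), sut2 (3.10 ± 0.26), retinin (2.52 ± 0.47) and TwdlE (2.36 ± 0.36), followed by the RNA-binding protein gene Hrb87F (2.05 ± 0.19) and dpr16 (1.94 ± 0.19, but 0.09 in its other, dim probe set). The largest falls were in blanks (-1.88 ± 0.20), Ekar (-1.70 ± 0.21), krimp (-1.62 ± 0.16), Dpp10 (-1.58 ± 0.32), GstD3 (-1.45 ± 0.20), superdeath (-1.15 ± 0.19), the acetylcholinesterase gene Ace (-1.07 ± 0.19) and Rdh1 (-1.06 ± 0.15). retinin, TwdlE, Dpp10, superdeath and Ace lost their calls in at least 1 removal, at adjusted p of 0.161 (without rbf120a replicate 1), 0.0554 (without the double mutant's replicate 1), 0.232 (without its replicate 3), 0.0761 (without rbf120a replicate 3) and 0.136 (without the double mutant's replicate 3). In total 81 genes changed, 41 higher and 40 lower. The count was 29, 45 and 46 without rbf120a replicates 1, 2 and 3, 38, 45 and 29 without the double mutant's, 137 and 159 without wtsX1Lats replicates 1 and 3, and 412 in a fit over these 6 arrays alone.

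What the rbf allele adds in a wtsX1Lats background was not detectable gene by gene. Allele and strain are not separated in this comparison either. With limma 0 genes passed, 1033 had an unadjusted p under 0.05 and the smallest adjusted p was 0.471. The E2F and DNA replication list had a median of 0.29 with 0 of 37 called (4 adjusted over the list alone; camera adjusted p = 6.43e-08, and adjusted p = 0.764 with an estimated correlation), while its medians in the arrays of wtsX1Lats ranged from 0.36 to 1.28 and its change was 0.618, 0.110 and 0.104 without replicates 1, 2 and 3. Other lists passing camera, each with 0 called members (between 0 and 2 higher, and 7 lower oxidative phosphorylation genes, when adjusted over the list alone), were morphogen and furrow signalling (median 0.27, adjusted p = 0.000597), ecdysone response and stage (0.36, 0.000453), retinal determination (0.18, 0.00122), oxidative phosphorylation (-0.21, 2.13e-07) and glycolysis (-0.15, 0.00454), and with an estimated correlation these were at adjusted p of 0.591, 0.419, 0.529, 0.419 and 0.419. The first 3 lost the call without wtsX1Lats replicate 1 (adjusted p = 0.463, 0.0502 and 0.163, with changes of -0.005, 0.020 and 0.081) and glycolysis did without the double mutant's replicate 3 (0.109, change of -0.099) and without wtsX1Lats replicate 3 (0.0738). Oxidative phosphorylation was at -0.132 without wtsX1Lats replicate 1, ecdysone response at 0.218 without the double mutant's replicate 2, and morphogen and retinal determination at 0.435 and 0.343 without wtsX1Lats replicate 3. The count of changed genes was 20 without wtsX1Lats replicate 1 and 1 without replicate 2, and 2 without replicates 1 and 3.

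Genes that set the double mutant apart from all 3 other groups were sought by requiring the same direction in its 3 comparisons. With limma 0 genes passed in all 3, and 24 higher and 41 lower genes had an unadjusted p under 0.05 in each. The 3 comparisons share the double mutant arrays, and no chance level was set for the unadjusted counts. Against wtsX1Lats the smallest limma adjusted p of any gene was 0.471. Against Canton S and rbf120a alone, 28 higher and 23 lower genes passed. ex and ey were among the 24, with ex at 1.13, 1.11 and 0.66 and ey at 0.91, 0.86 and 0.58 against Canton S, rbf120a and wtsX1Lats. Without wtsX1Lats replicate 1, 1 gene passed, CG11370, which was named after its values were seen.

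The rbf120a effect was compared between the 2 backgrounds, which share no array. Across 11982 genes, which are not independent replicates, the change in Canton S and the change in wtsX1Lats had Pearson r = 0.103 and Spearman rho = 0.057. The jackknife SE of r over the 12 arrays, 0.132, exceeds r, which was 0.024 without the double mutant's replicate 1, 0.047 without Canton S replicate 2, 0.057 without wtsX1Lats replicate 2 and 0.167 without the double mutant's replicate 2. Of the 215 genes higher in rbf120a, 140 were above 0 in the wtsX1Lats background, with a median change of 0.09 there against 0.93 in Canton S. Of the 205 lower genes, 110 were below 0 there, with a median of -0.02 against -0.91. The median over all genes there was -0.02 as well. Both sets were chosen by their call in the Canton S background, so a smaller change in the other background follows in part from that choice. They include the 221 genes changed alike in all 3 mutant groups, and a change common to wtsX1Lats and the double mutant cancels in their difference. These medians therefore do not show that the rbf120a effect is lost.

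A test of the difference itself, the interaction, passed in 107 genes, 59 positive and 48 negative. Positive values were largest for Mec2 (3.39 ± 0.60 SE), Glt (3.15 ± 0.22), srp (2.88 ± 0.60), fat-spondin (2.85 ± 0.48), Hrb87F (2.65 ± 0.26) and eater (2.60 ± 0.42), and negative ones for Mal-A1 (-2.84 ± 0.52), LBR (-2.64 ± 0.20), Gr61a (-2.29 ± 0.32), krimp (-2.19 ± 0.22), jim (-2.11 ± 0.10) and blanks (-2.02 ± 0.29). The other 2 probe sets of jim gave 0.39 and 0.61, opposite in sign to the one used. Of the 107 genes, 81 were also among the genes changed the same way in all 3 mutant groups against Canton S. In all 81 the interaction had the sign opposite to the rbf120a change. Changes of about equal size in the 3 groups give that sign whatever their cause. Of 100 drawn splits that kept the Canton S arrays together and mixed the mutant arrays, 19 gave at least 107 genes. The count was 41 without Canton S replicate 1, 60, 46 and 43 without the double mutant's replicates 1, 2 and 3, and 54, 58 and 54 without rbf120a replicates 1, 2 and 3. Mec2, srp, fat-spondin and eater lost the call without Canton S replicate 1 (adjusted p = 0.0714, 0.141, 0.0618 and 0.0504) and Mal-A1 without the double mutant's replicate 2 (0.0875).

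The single mutants were compared by the calls they have in common against Canton S. Both were higher in 101 genes and lower in 148, where independent lists would share 4.9 and 6.8, and 0 genes moved in opposite directions. The changes correlated at r = 0.679 across genes, with a covariance of 0.0822. Simulated unchanged groups against the same Canton S arrays gave r = 0.503, a covariance of 0.0169 and a mean of 0 shared calls. The simulation drew genes independently, and the 3 control arrays cannot be split with at least 2 in each part. Part of the excess may therefore still come from the shared controls. A strain difference common to the mutant groups would be shared as well, and the design does not separate it from the alleles. All 3 mutant groups were higher than Canton S in 88 genes and lower in 133. The shared count of 249 was 118 without Canton S replicate 1 and 154, 155 and 155 without rbf120a replicates 1, 2 and 3.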

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

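Of the tests below, those for a wrong label, all tests of wtsX1Lats replicate 3, those for fewer blood or fat body cells, the one of weak signal in the whole blood cell list, the one of second probe sets and the splits that keep Canton S together were chosen after the result was seen; the others were planned before. Groups of 3 arrays are too small for a test of single outlying arrays.

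A difference between the rbf120a effects in the 2 backgrounds brought 107 genes to notice. The genes with named values were Mec2 (3.39), Glt (3.15), srp (2.88), fat-spondin (2.85), Hrb87F (2.65), eater (2.60), stv (2.27) and Hml (2.10) on the positive side, and Mal-A1 (-2.84), LBR (-2.64), Gr61a (-2.29), krimp (-2.19), jim (-2.11, but 0.39 and 0.61 in its other 2 probe sets) and blanks (-2.02) on the negative side. List medians of the same difference passed camera for E2F and DNA replication (-0.65), mitosis (-0.25), Hippo pathway components (0.27), photoreceptor and cone cell differentiation (0.28), retinal determination (0.30), morphogen and furrow signalling (0.35), ecdysone response and stage (0.31), glycolysis (-0.16), oxidative phosphorylation (-0.25), blood cells (0.31) and gut (-0.49). With an estimated correlation their adjusted p lay between 0.331 and 0.766. A list that moved by about as much in all 3 mutant groups also takes the opposite sign in this difference. Against Canton S, the E2F and DNA replication medians were 1.04, 0.66 and 1.10 in rbf120a, wtsX1Lats and the double mutant. Those of blood cells were -0.54, -0.59 and -0.79. Several of the list calls rested on single arrays. Without wtsX1Lats replicate 1 the medians were -0.355 for E2F and DNA replication, 0.041 for photoreceptor, 0.105 for morphogen and furrow, 0.143 for retinal determination, 0.145 for ecdysone response and -0.148 for oxidative phosphorylation, and the photoreceptor and morphogen calls ended (camera adjusted p = 0.585 and 0.191). Without wtsX1Lats replicate 3 the photoreceptor, retinal determination and blood cell medians were 0.513, 0.46 and 0.613. The gut call ended without rbf120a replicate 3 (median -0.117, camera adjusted p = 0.137) and without Canton S replicate 2 (0.051), which also took the morphogen and furrow median to 0.19, and the glycolysis call without the double mutant's replicate 3 (0.067).

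Of 100 splits of the 12 arrays into 4 groups of 3, the real one included, 2 gave as many genes as the real 107, and the highest other split gave 306. That split kept the 3 Canton S arrays together and mixed the mutant arrays, which points to a structure of the samples. In 100 further splits of that kind the median was 60.5 genes, the highest 576, and 19 reached the real count. In 100 splits that mixed Canton S with the mutants the median was 0, the highest 55, and 0 reached it. The count is therefore consistent with Canton S standing apart from all mutant groups, and chance is not excluded for the grouping of the mutant arrays. For the double mutant against all 3 others, all 100 splits reach a real count of 0 by necessity, so they decide nothing, and the highest other gave 7. For the comparisons of 3 with 3 arrays there are 10 splits, too few for a test.

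Probe sets with no single gene were left out of the comparisons, and of 5123 such probe sets 64 were higher and 55 lower than Canton S in rbf120a, 45 and 62 in wtsX1Lats and 60 and 57 in the double mutant.

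The first pattern is a set of 221 genes that changed alike in all 3 mutant groups against Canton S, with median changes of 1.09, 0.96 and 1.03 for the higher genes and -0.99, -1.04 and -1.04 for the lower ones. A strain difference confined to 1 arm is argued against, since the arm with the most genes held 26.2%, and a sequence difference under single probe sets, as the values of jim and of RFeSP (0.21, 0.42 and 0.21 in the probe set used, -4.95, -4.92 and -4.95 in its other one) might suggest, cannot be told apart, because 6 of the genes had a second probe set with enough signal; 83.3% of those (95% interval 35.9 to 99.6) kept at least 0.5 of the change. Fewer blood cells would lower genes, so the 88 higher genes argue against that cause for them. For the 133 lower genes it cannot be told apart: 61.5% of the 13 blood cell genes with a Canton S mean above 7 lay below -0.5, but called genes are among them. The same holds for fewer fat body cells, where 2 of the 8 measured genes reached that level (50% lay below -0.5) and the list's medians were 0.08, 0.04 and 0.05. Of the 221 genes, 2 were among the 16 measured blood cell genes and 1 among the 8 fat body genes. These lists are short, so the counts do not measure the share of blood or fat body genes in the set. The higher genes include all 7 members of the E2F and DNA replication list that were called in wtsX1Lats. A genome-wide strain difference and an effect common to all mutant discs stay open, and the design does not separate them.

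The second pattern is the lower signal of blood cell genes in all 3 mutant groups. Weak signal is argued against by the whole list, where 93.8% of the 16 measured genes had Canton S means above the 40th percentile of probe sets; that 100% of the passing genes did decides nothing, as they were chosen by their fall. Fewer attached blood cells cannot be told apart: the median change of Hml, NimC1, eater, Pxn and PPO1 was -2.02, -1.05 and -1.25 in rbf120a, wtsX1Lats and the double mutant, so the smallest fall was -1.05, but genes already called lower are among the 5. The fixed list had medians of -0.54, -0.59 and -0.79, and a lower expression within blood cells stays open.

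The third pattern is the spread within wtsX1Lats, where replicate 1 lay below all other arrays in 8 of 30 list medians and above them in 5 (among them E2F 1.28, photoreceptor -1.09, morphogen -0.687, ecdysone -0.439, JNK -0.373, muscle -0.943 and antennal disc -0.545) and replicate 3 above them in 6 (among them Hippo targets 0.459, antennal disc 0.30 and muscle 0.93), though Canton S replicate 2 did so too, below in 5 and above in 6. An rbf120a array under a wrong label is argued against, since 88.9% and 80.2% of the 81 genes that differ between rbf120a and the double mutant lay closer to the double mutant in replicates 1 and 3, although over genes with a mean above 7 replicate 3 lay nearest to the rbf120a mean (0.218) and its closest array was rbf120a replicate 3 (r = 0.9896, against at most 0.9883 with its own group). A double mutant array cannot be told apart, because both arrays lay far from every group, their own included (0.373 and 0.231 from the double mutant, 0.373 and 0.325 from their own). In replicate 3 the 3' minus 5' differences lay above all other arrays in 3 of 3 control genes, consistent with RNA degradation or a difference in labelling there; in replicate 1 they did so in 0 of 3 (0.32, 1.11 and 0.58, at or below the lowest), which leaves a difference in labelling open. More of another tissue is argued against in replicate 1, with a largest excess of -0.043 over the other 11 arrays. Some of those arrays were high themselves (up to 1.653 for salivary gland), but the list medians of replicate 1 reached at most 0.084 (gut) relative to Canton S. More of another tissue cannot be told apart in replicate 3 (0.31, muscle). Less attached muscle or antennal disc in replicate 1 stays open, and disc age or the share of mutant cells stays open and was not tested.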

How the results depend on the processing

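The gene-by-gene array weights and the removal of wtsX1Lats replicates 1 and 3 together were added after seeing the data. The direction and call of the 9 leading results, in the order rbf120a, wtsX1Lats and the double mutant against Canton S, the double mutant against rbf120a and against wtsX1Lats, interaction, against all 3 others, overlap of the single mutants and the correlation of rbf120a effects, stayed within 1.5 times of 420, 672, 658, 81, 0, 107, 0, 249 and 0.103 under a second quantile normalization, median centring, the removal of dim genes, the mean of probe sets, no variance trend, the array number block and all probe sets. With the replicate number as a block the counts were 388, 674, 620, 61, 0, 87, 0 and 245. The numbers do not pair the samples: 6 of 18 same-number pairs had correlated deviations above 0.1 (range -0.298 to 0.311), and 3 of 12 arrays matched their own number best. Where a count moved, the cause was not tested unless fewer arrays or a fold minimum explain it. Arrays 1 to 8 alone gave 201, 329, 18, 38 and 141 (rbf120a, double mutant, double mutant against rbf120a, interaction, overlap). A change of at least 1 left 184, 231, 258, 36 and 101 (3 groups against Canton S, double mutant against rbf120a, overlap). Default array weights gave 3215, 4464, 589, 248 and 632 (as for arrays 1 to 8) but did not converge and gave Canton S replicate 1 a weight of 28.8. Gene-by-gene weights gave 1419, 1297, 2329, 481, 4, 301, 1 and 572, the 4 genes being tko, del, elg1 and Zip102B and the 1 gene del, named after their values were seen. Without wtsX1Lats replicates 1 and 3, which leaves 1 array of the group, assumed to vary like the others, the counts were 794, 311, 1400, 240, 2 (tko and Zip102B), 55 and 163, with 0 against all 3 others. Fits over the groups of a contrast alone gave 181, 1076 and 412 for wtsX1Lats and the double mutant against Canton S and the double mutant against rbf120a, and an overlap of 100. Without each array in turn the ranges were 197 to 632, 297 to 1596, 297 to 1080, 29 to 159, 0 to 20, 41 to 121, 0 to 1 and 118 to 335, and the correlation lay between 0.024 and 0.167. The single gene for the double mutant against wtsX1Lats without wtsX1Lats replicate 2 was Ulp1.

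The following changed sign. Of these, 2 were lists that passed, morphogen and furrow signalling and DNA damage response and repair for the double mutant against wtsX1Lats. The E2F and DNA replication median for the double mutant against rbf120a went from -0.005 to 0.007, 0.022 and 0.015 under quantile normalization, centring and array weights, and without single arrays lay between -0.051 and 0.11. On arrays 1 to 8, the change of Rbf, wtsX1Lats against Canton S, was -0.227, the DNA damage median for the double mutant against wtsX1Lats at -0.025 and the Hippo target interaction at 0.096. wts in the double mutant was at 0.061 with array weights and 0.031 with gene-by-gene weights. Without single arrays, Rbf in wtsX1Lats lay between -0.256 and 0.432, wts in wtsX1Lats between -0.534 and 0.062 and in the double mutant between -0.095 and 0.032. Hippo target medians lay between -0.034 and 0.057 in rbf120a, -0.086 and 0.141 for the double mutant against wtsX1Lats, and -0.135 and 0.003 for the interaction. For the double mutant against wtsX1Lats the ranges were -0.016 to 0.117 (mitosis), -0.147 to 0.351 (photoreceptor), -0.005 to 0.435 (morphogen and furrow) and -0.012 to 0.18 (DNA damage). The cause was not tested.

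Of the named calls, 23 of 33 genes in rbf120a, 34 of 53 in wtsX1Lats and 30 of 50 in the double mutant held against Canton S without every array in turn, as did 11 of 20 for the double mutant against rbf120a and 9 of 14 interactions. Of the list calls 4 of 6, 7 of 10, 8 of 10, 7 of 10 and 7 of 11 held, and 2 of 9 for the double mutant against wtsX1Lats. With an estimated correlation 56 list calls were lost. Without detection calls, dim genes could not be separated from background.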

Other observations

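Several lists did not pass camera, though some had called members. Apoptosis (11 genes; medians 0.08, -0.07 and -0.02 in rbf120a, wtsX1Lats and the double mutant against Canton S), JNK and wounding (16; 0.12, -0.03 and -0.05), ribosome biogenesis (21; -0.03, 0.10 and 0.06) and ribosomal proteins (41; 0.00, 0.03 and 0.01) passed camera in none of the 6 comparisons (lowest adjusted p = 0.0652). Against Canton S, the same held (lowest adjusted p = 0.0749) for heat shock (5; 0.51, 0.16 and 0.57), antimicrobial peptides (8; 0.13, -0.01 and 0.00), germline genes (16; 0.05, 0.06 and 0.05), testis (14; 0.03, 0.08 and 0.02), fat body (8; 0.08, 0.04 and 0.05), trachea (5; -0.02, -0.08 and 0.05), salivary gland (9; 0.34, 0.25 and -0.36), muscle (10; 0.25, -0.25 and -0.37), the 1 male sex marker (0.81, 0.40 and 0.62) and the eye disc markers of late differentiation (7; 0.01, -0.05 and -0.09). In heat shock stv fell in all 3 groups, and in rbf120a and the double mutant 3 of 5 genes were higher and 1 lower when adjusted over the list alone. The heat shock list kept 5 of its 16 written symbols, without the Hsp70 genes, and the apoptosis list lacked rpr, hid, Ice and th. Germline genes had 2 higher members of 16 in each group (4, 5 and 3 adjusted over the list alone, with 1 lower in rbf120a), krimp and AGO3 in rbf120a, and fry adjusted p of 0.0202, 0.0701 and 0.0608. Among late differentiation markers 1 of 7, st, fell in each group (1, 1 and 2 adjusted over the list alone), with fry adjusted p of 0.181, 0.0102 and 0.00207. Median, mean and test differed in sign only where a list did not pass camera.

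Several further lists passed camera and lost the call in some removal of an array. Morphogen and furrow signalling (10 genes, 0 called, 0 adjusted over the list alone) was at -0.32 in wtsX1Lats (camera adjusted p = 0.0127, and adjusted p = 0.511 with an estimated correlation), and at -0.101 and camera adjusted p = 0.377 without wtsX1Lats replicate 1 and -0.516 and 0.00013 without replicate 3. The antennal disc list (12 genes) was at -0.24 there with 2 called and 2 adjusted over the list alone (camera adjusted p = 0.00949, and adjusted p = 0.511 with an estimated correlation), and at -0.34 in the double mutant with 0 and 3 (0.0314 and 0.732). The first was at -0.120 (0.374) without wtsX1Lats replicate 1, at 0.0669 without replicate 2 and at -0.483 (1.22e-06) without replicate 3, and the second at 0.146 without the double mutant's replicate 1. Glycolysis was at 0.20 in the double mutant against Canton S (0 of 10 called, 0 adjusted over the list alone; camera adjusted p = 0.0156, and adjusted p = 0.26 with an estimated correlation), and at 0.0953 without the double mutant's replicate 1. Against rbf120a, ecdysone response and stage (0.11; 0.0363) and glycolysis (0.10; 0.0479) passed camera with 0 called members and 0 adjusted over the list alone, both with adjusted p = 0.404 with an estimated correlation. The first fell to 0.021 (0.388) without the double mutant's replicate 2 and to 0.050 (0.101) without rbf120a replicate 3, and the second to 0.058 (0.244) without the double mutant's replicate 1, with its call lost in 10 of 12 removals. Against wtsX1Lats, Hippo pathway components (12 genes; 0.20; 0.0329), DNA damage response and repair (0.07; 0.0258) and heat shock (0.41; 0.0277) passed with 0 called and 0, 1 and 0 adjusted over the list alone. Their adjusted p with an estimated correlation were 0.419, 0.73 and 0.529, and the calls ended without wtsX1Lats replicates 1, 3 and 2 (0.49, 0.203 and 0.445, with changes of 0.055, -0.012 and 0.135). The DNA damage change was also at 0.032 and 0.117 without the double mutant's replicates 1 and 2 and 0.18 without wtsX1Lats replicate 1, and heat shock at 0.258 without the double mutant's replicate 2.

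Medians of some lists of other tissues were uneven among replicates, and whether tissue in the samples gave rise to this was not tested. The salivary gland median stood at 1.65 in rbf120a replicate 2 and 1.03 in wtsX1Lats replicate 3, and the gut median at 0.96 in rbf120a replicate 3.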
